A study of Arabidopsis thaliana with 10 samples.

How the data were processed

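The study measured transcripts in Arabidopsis thaliana Col-0 on 10 Agilent 2-colour arrays of the 4x44K format. Each array carried an altered genotype in 1 dye and wild type in the other: 35S:HSFB1 roots (n = 3), 35S:mutHSFB1 roots (n = 3) and hsfb1 hsfb2b whole seedlings (n = 4). Per the labels, plants grew on MS agar at 22 °C with 16 h of light, roots were taken at 22 days and seedlings at 7 days. The labels call the arrays of a group biological replicates, and nothing beyond those labels says that they came from separate cultures. The genotype was in Cy5 on replicate 1 of both root lines and on replicates 1 and 3 of the seedlings, and in Cy3 on the others. In the roots the dyes are therefore unbalanced. Replicates 2 and 3 of both root lines shared a slide, 35S:HSFB1 replicate 1 lay on another, the slide of 35S:mutHSFB1 replicate 1 is not given, and the seedling arrays shared 1 slide. In the roots slide and dye orientation are confounded. Root arrays with the same replicate number correlated at 0.513, -0.164 and -0.159 after each line's mean was removed. Of arrays with unequal numbers, 35S:HSFB1 replicate 3 and mutated replicate 2 were at 0.579, and 35S:HSFB1 replicate 2 and mutated replicate 3 at 0.294. The other pairs lay between -0.497 and -0.0946. Equal numbers thus do not pair the lines throughout. Pairing in another order cannot be told, and both replicate 1 arrays share a dye orientation.

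The submitters' processing notes name Agilent Feature Extraction 9.1. The deposited array files hold spot and local background signal per dye as intensity, along with processed signals that the software had corrected for background and dye. They also give the log10 ratio of Cy5 over Cy3 of the processed signals, per the file headers. The series matrix holds the same log10 ratio, turned by the authors to genotype over wild type, with a median of 0 on every array and a difference of at most 0.005 from the array files. Each array had 39102 features. Of the 37478 probes that are not controls, 26236 carried a gene locus (25665 loci) and 11242 did not, 8812 of these being genome-region probes. Of the loci, 25449 were matched to the gene reference of assembly TAIR10.1, which was used only for names and for which genes are neighbours. Gene symbols follow the lists and that reference. Between 59.1% and 65.2% of spots per channel were well above background, 15 to 141 spots per array were marked as outliers by the software and none were saturated.

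Signals were background corrected with normexp (offset 50) and normalised by loess within arrays in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the data.table package and statmod 1.5.0). Control spots and outlier-marked spots were left out, spots of 1 probe were averaged, and a gene was represented by its brightest probe. The seedling files hold no mean signal column, so median signal was used there and mean signal on the root arrays, which departs from what was planned. Probes had to be well above background on every array of a group in the altered or the wild type channel. The 6 root arrays were fitted together and the 4 seedling arrays on their own, with lmFit, a dye coefficient and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05 over genes. The difference between the root lines was a contrast of the same fit. Median SE was 0.0846 in the roots, 0.116 for the difference and 0.0439 in the seedlings. A fold of "at least" is given where a gene was not well above background in a channel on any array of the group.

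On simulated data with known changes, 67% of genes changed by log2 1 and 89% of those changed by log2 2 were called with the right sign for 35S:HSFB1 (19910 genes). The shares were 67% and 93% for 35S:mutHSFB1, 59.6% and 86.5% for the difference, and 94% and 99% for the seedlings (19401 genes). False calls made up 4.29%, 2.44%, 4.28% and 2.53% of calls. The simulation changed 200 genes per group and drew noise independently for each spot and array. These shares need not hold where fewer or more genes change, as in 35S:HSFB1 roots with 5458 genes called, or where genes vary together. Simulated changes of log2 1 had a median estimate of 0.885 in 35S:HSFB1 and 0.947 in the seedlings, so fitted fold changes and 2-fold counts run low.

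The comparisons, tests, gene lists and named genes were chosen before the data were examined. Named were, per comparison, HSFB1 and HSFB2B, the 10 highest and 10 lowest fold changes among genes past the threshold with the same sign on every array, the tested heat shock factors, and up to 3 genes past the threshold from each other list or its largest change. Where no gene passed in a direction, the 5 with the lowest p in that direction were taken. The 20 lists (317 loci) covered the heat shock factor family, small HSPs, HSP70 with HSP90 and HSP100, other heat-induced genes, folding in the endoplasmic reticulum, jasmonate and ethylene, salicylate, abscisic acid, oxidative stress, photosynthesis, the circadian clock, root hairs, endodermis and suberin, iron, phosphate, nitrate, auxin, cell division, seed storage and housekeeping. Lists were tested with limma's camera at a preset correlation of 0.01, for at least 3 tested members, and again with an estimated correlation. The estimated form rests on the fit's residual degrees of freedom, 3 in the roots and 2 in the seedlings. It can therefore lose a call even where list members do not vary together. Overlaps were tested with Fisher's exact test.

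The alternatives were no background subtraction, the scanner software's log ratio, the series matrix values, quantile normalisation of average intensity, no filter and a stricter filter on dim probes, outlier-marked spots kept, the mean of a gene's probes, no dye coefficient, eBayes with trend and robust, array weights, each root line's arrays alone, all 10 arrays in 1 fit, slide as a random block, replicate as a block, and each array left out in turn. Median signal on the root arrays, fits within the shared slide with their list tests, the overlap with arrays left out, within the shared slide and without the targeted genes, and the heat shock factor list without its targeted genes were added after the data were seen. So was the tolerance for a moved correlation, the spread between leave-out values. Each targeted gene has 1 probe, so a probe alternative for them did not apply. Probes without a locus were left out of the comparisons because they name no gene. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.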

Results

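Transcript levels were measured in Arabidopsis thaliana Col-0 on 10 Agilent 2-colour arrays, each of which set RNA of a genetically altered line against RNA of wild type plants. HSFB1 and HSFB2B are class B heat shock factors, which bind heat shock elements but lack the activation motif of class A factors and act as repressors. Roots of 22-day-old plants were compared for a line with HSFB1 under the 35S promoter (35S:HSFB1, n = 3 arrays) and a line with a mutated HSFB1 under the same promoter (35S:mutHSFB1, n = 3). Whole seedlings 7 days old were compared for a knockout of both genes (hsfb1 hsfb2b, n = 4). All plants grew at 22 °C, without heat stress. The number of arrays limits the precision. Fold changes are log2 values of the altered line over wild type with the standard error (SE) of the fit, and adjusted p-values are from limma.

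The targeted genes were examined first. HSFB1 (AT4G36990) rose 30.0-fold in 35S:HSFB1 roots (log2 4.91 ± 0.20, SE, n = 3, adjusted p = 1.11e-04) and 34.8-fold in 35S:mutHSFB1 roots (5.12 ± 0.20, n = 3, adjusted p = 0.00382). The difference between the lines, -0.21 ± 0.27, was within its error (adjusted p = 0.698). The gene has 1 probe, which does not tell transgene from endogenous transcript. In the mutated line the call was lost without replicate 1, at 5.24 with an adjusted p of 0.209. In hsfb1 hsfb2b seedlings HSFB1 fell by 2.67 (± 0.15, n = 4, adjusted p = 8.11e-04) and HSFB2B (AT4G11660) fell by 1.17 (± 0.09, adjusted p = 0.00302). The HSFB2B probe was well above background in the knockout channel on 2 of the 4 arrays, and where either probe lies relative to an insertion is not known. With the scanner software's own log ratio the HSFB2B value was -3.73 and no longer passed the threshold (adjusted p = 0.123). In roots HSFB2B did not pass the threshold in 35S:HSFB1 (-0.21 ± 0.12, adjusted p = 0.233) or in 35S:mutHSFB1 (0.46 ± 0.12, adjusted p = 0.436), but the lines differed by -0.68 ± 0.16 (adjusted p = 0.0392), a call lost without 35S:HSFB1 replicate 1 or mutated replicate 1 (-0.67 each, adjusted p = 0.175), 35S:HSFB1 replicate 2 (-0.63, adjusted p = 0.0513) or mutated replicate 3 (-0.52, adjusted p = 0.129).

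The highest gene in 35S:HSFB1 roots was CYP71A12 (AT2G30750), a cytochrome P450 of camalexin and indole-carbonyl synthesis, which rose 69.8-fold (log2 6.12 ± 0.26, n = 3, adjusted p = 1.11e-04). CDEF1 (AT4G30140), a cutinase that acts on the cuticle and the endodermal suberin of emerging lateral roots, rose by 5.03 ± 0.08 (adjusted p = 1.24e-05). The lipase gene PLA2A (AT2G26560), induced in defence, rose by 4.70 ± 0.26. CYP706A1 rose by 4.87 ± 0.11, the methyltransferase gene CCOAMT by 4.78 ± 0.25 and the PR1-like gene AT4G33720 by 4.34 ± 0.20. CCOAMT was well above background in the wild type channel on 2 of the 3 arrays. The unnamed genes AT5G40590 and AT5G22555 rose by 5.43 ± 0.23 and 4.58 ± 0.20. The lowest gene was MRN1 (AT5G42600), which makes the triterpene marneral, at -4.02 ± 0.24 (adjusted p = 2.70e-04). The ammonia-permeable aquaporin gene TIP2;3 fell by 3.88 ± 0.34, CYP712A1 fell by 3.83 ± 0.25 and the glutathione transferase gene GSTF14 fell by 3.31 ± 0.16. The drought gene RD20 was at -3.78 ± 0.46 (adjusted p = 0.00238) and the jasmonate synthesis gene LOX2 at -3.75 ± 0.82 (adjusted p = 0.0196). The LOX2 call was lost without replicate 1.

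Among 19911 genes tested, 5458 (27.4%) passed the threshold of 0.05 in 35S:HSFB1 roots, 2693 higher and 2765 lower. The list counts for this line are to be read against that share. Of these, 1031 changed at least 2-fold, 725 upward and 306 downward, and 5368 had the same direction on all 3 arrays. The number was 1731 (1172 higher and 559 lower) without replicate 1, which also took 25 of the 76 named genes past the threshold out of it, and 2430 when only the 3 arrays of this line were fitted. Without replicate 1 the dye coefficient is set by replicate 1 of the mutated line alone. Within the shared slide, which also lacks replicate 1, the number was 3827 (2125 higher and 1702 lower). All arrays there had the genotype in Cy3, so dye bias could not be fitted and stays in that number. Replicate 1 was the only array of the line with the altered genotype in Cy5, and it lay on another slide than replicates 2 and 3, so slide and dye cannot be told apart.

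Salicylate genes rose as a group in 35S:HSFB1 roots. Of 14 salicylate defence genes tested, 10 rose and none fell, and 13 rose when adjusted over the list alone. PBS3 (AT5G13320), which conjugates isochorismate to glutamate in salicylate synthesis, rose 10.7-fold (log2 3.42 ± 0.14). The transcription factor genes WRKY38 and WRKY54 rose by 2.61 ± 0.23 and 2.52 ± 0.11. The list was higher than other genes by camera (adjusted p = 1.98e-06). That call was lost at adjusted p = 0.814 with an estimated correlation. In the other direction, 8 of 18 endodermis and suberin genes fell and 1 rose, or 11 fell and 1 rose when adjusted over the list alone. They included the Casparian strip membrane proteins CASP5 (-0.73 ± 0.16) and CASP2 (-0.72 ± 0.10), both of which lost their calls without replicate 1. Camera placed this list below other genes (adjusted p = 0.00311). That call was also lost, at adjusted p = 0.814 with an estimated correlation.

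**Figure D1:**
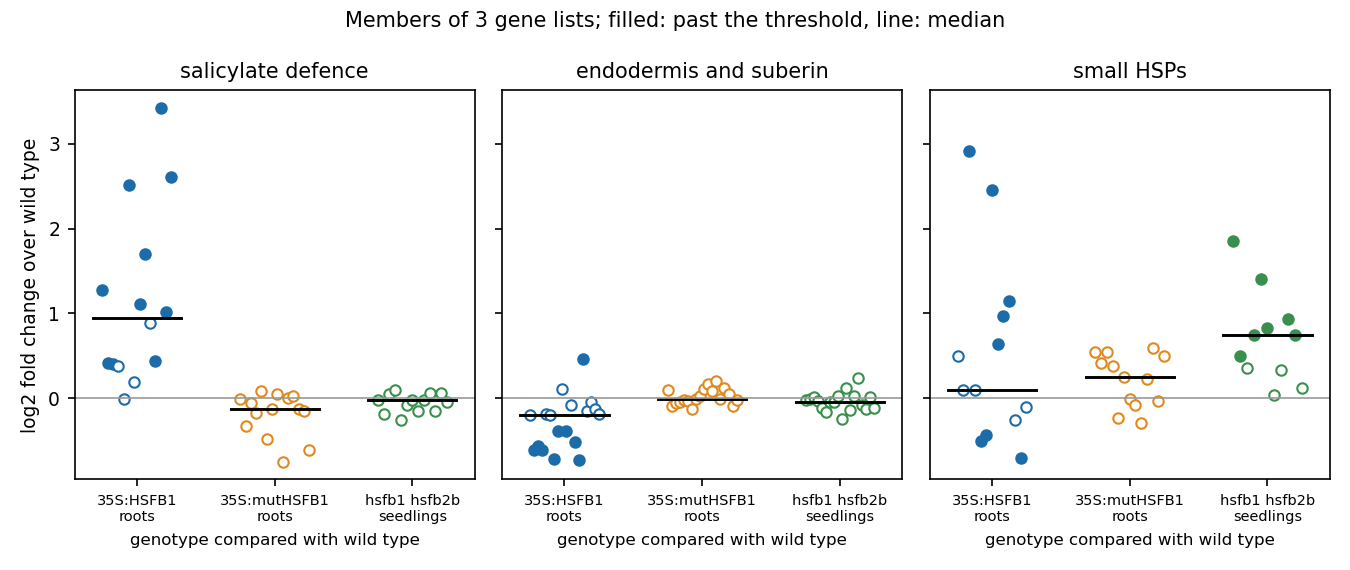
Log2 fold change over wild type of the tested members of 3 gene lists, 1 circle per gene, for 35S:HSFB1 roots (n = 3 arrays), 35S:mutHSFB1 roots (n = 3) and hsfb1 hsfb2b seedlings (n = 4). Filled circles passed the adjusted p threshold and lines are list medians, which were 0.95 for salicylate genes in 35S:HSFB1 roots and 0.74 for small HSP genes in the knockout.

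Heat shock factor genes moved in both directions in 35S:HSFB1 roots. HSFA6B rose by 1.53 ± 0.10, HSFA8 by 1.02 ± 0.08 and HSFC1 by 0.55 ± 0.12. HSFA4A fell by 1.52 ± 0.11, HSFA7A (AT3G51910) fell by 1.31 ± 0.20 and HSFA3 fell by 0.36 ± 0.08. HSFA2, the main heat-inducible activator, was at 0.12 ± 0.22 (adjusted p = 0.724). With HSFB1 itself, 4 of 19 tested members of the family rose and 3 fell, or 4 and 4 when adjusted over the list alone. The calls of HSFA7A, HSFC1 and HSFA3 were lost without replicate 1.

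Small heat shock protein (HSP) genes also split. HSP17.6C-CI (AT1G53540) rose by 2.91 ± 0.15 and HSP17.4-CI by 2.46 ± 0.18, while of the 13 small HSP genes tested 5 rose and 3 fell, also when adjusted over the list alone. HSP17.7-CII rose at least 2.30-fold (adjusted p = 0.0485), a call lost without replicate 1. Class I small HSP genes are related in sequence, and how far a probe reads more than 1 of them was not examined. Of 19 HSP70, HSP90 and HSP100 genes 5 rose and 2 fell (5 and 4 adjusted over the list alone), with HSP70-5 at 1.78 ± 0.09, HSP90.1 at 1.31 ± 0.17 and HSP70-2, which has a near-identical copy, at 1.06 ± 0.21. Of 14 other heat-induced genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with GOLS1 at 1.77 ± 0.12, BAG6 at 1.27 ± 0.13 and DREB2B at 1.04 ± 0.12. None of these lists passed camera (adjusted p = 0.336 for small HSPs, 0.967 for HSP70, HSP90 and HSP100, and 0.0908 for other heat-induced genes). For HSP70, HSP90 and HSP100 the median (-0.098) and the mean (0.10) differed in sign.

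Nitrogen, iron, phosphate and auxin genes changed as single genes. The nitrate transporter gene NRT2.1 (AT1G08090) rose 13.3-fold (log2 3.73 ± 0.15), while nitrate reductase NIA1 and nitrite reductase NIR1, which act after uptake, fell by 2.08 ± 0.10 and fell by 1.79 ± 0.09. In that list of 6 genes 1 rose and 4 fell, also when adjusted over the list alone. The scopoletin synthesis gene F6H1 rose by 2.47 ± 0.11, the nicotianamine synthase gene NAS2 rose by 2.43 ± 0.09 and the copper transporter gene COPT2 fell by 1.95 ± 0.21, among 6 higher and 3 lower of 19 iron deficiency genes (8 and 3 adjusted over the list alone). The phospholipase gene PLDZ2 rose by 1.73 ± 0.20, SPX1 by 1.41 ± 0.13 and the non-coding AT4 by 1.17 ± 0.10, among 6 higher and 4 lower of 15 phosphate starvation genes, also when adjusted over the list alone. GH3.3, which conjugates auxin, rose 18.4-fold (log2 4.21 ± 0.57), and LBD16, required for lateral root initiation, rose by 1.69 ± 0.09. In all 5 of 10 auxin genes rose, also when adjusted over the list alone, and GH3.5, at 0.92 ± 0.14, was no longer called without replicate 1.

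Members of the remaining lists also changed in 35S:HSFB1 roots. As 27.4% of all tested genes passed in this line, counts near or below that share, such as 3 of 13 clock genes, do not set a list apart. The housekeeping genes, with 2 higher and 2 lower of 10, were above it. Of 19 jasmonate and ethylene genes 5 rose, among them the chitinase gene CHIB (2.31 ± 0.09) and JAZ9 (1.66 ± 0.13), and 4 fell, or 8 and 6 adjusted over the list alone. Of 14 abscisic acid genes 1 rose (RD29A, 0.61 ± 0.10) and 5 fell (with COR47 at -0.92 ± 0.12), also when adjusted over the list alone. Of 14 oxidative stress genes 4 rose and 3 fell, or 5 and 3 adjusted over the list alone, with UPOX at 1.42 ± 0.41, UGT73B5 at -1.13 ± 0.08 and CSD1 at 0.87 ± 0.22. Of 14 endoplasmic reticulum folding genes BIP3, well above background in the wild type channel on 1 of the 3 arrays, rose by 0.59 ± 0.10, and ERDJ3A and BZIP28 fell by 0.78 ± 0.16 and 0.61 ± 0.09, with the same 1 and 2 when adjusted over the list alone. The clock genes CCA1 (0.95 ± 0.11), PRR7 (0.77 ± 0.09) and RVE8 (0.58 ± 0.09) were the 3 that rose among 13, also when adjusted over the list alone. Of 14 root hair genes XTH12 and RSL4 rose (0.86 ± 0.23 and 0.58 ± 0.13) and RHS19 fell by 0.67 ± 0.16, 2 and 1 also when adjusted over the list alone. RBCS3B (-1.40 ± 0.30), LHCA2 (-0.57 ± 0.17) and GLK1 (at least 1.24-fold lower) fell among 22 photosynthesis genes, where none passed when adjusted over the list alone, and the RBCS genes are near-identical copies. None of 15 cell division genes passed, over all genes or adjusted over the list alone. The seed storage gene EM6, the 1 member tested, rose by 0.61 ± 0.10. Of 10 housekeeping genes ACT8 was among 2 that rose (0.40 ± 0.07), and ACT7 (-0.40 ± 0.07) and GAPC1 (-0.48 ± 0.11) fell, 2 and 2 also when adjusted over the list alone. None of these lists passed camera (lowest adjusted p = 0.0562, photosynthesis). Without replicate 1 only CHIB, JAZ9, COR47, UGT73B5, BIP3, CCA1 and PRR7 among the genes named here kept their calls. LHCA2 was also lost without replicate 2, and GLK1 and RHS19 without replicate 3. LHCA2 (0.061 on replicate 3) and RHS19 (0.022 on replicate 2) did not have the same sign on every array.

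Overexpression of mutated HSFB1 left no gene other than HSFB1 past the threshold in roots. The heat genes nearest to it were HSP101 (1.26 ± 0.13, n = 3, adjusted p = 0.145) and DREB2A (1.15 ± 0.14, adjusted p = 0.145). HSFA2 was at 1.05 ± 0.22 (adjusted p = 0.316), HSFB2A at 0.94 ± 0.16 (adjusted p = 0.224) and the chaperone gene ERDJ3A at 1.00 ± 0.16 (adjusted p = 0.202). The 5 genes with the lowest p among those below wild type were the P450 gene CYP712A2 (-1.46 ± 0.13), AT1G52790 (-1.33 ± 0.14), the xylosidase gene BXL2 (-0.74 ± 0.08), GPAT1 (-0.67 ± 0.07) and UMAMIT35 (-0.64 ± 0.06), each at an adjusted p of 0.145, which does not pass.

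Of 19911 genes, 1 passed in limma and 1159 had an unadjusted p under 0.05, against 7869 in 35S:HSFB1 roots. The count changed with the arrays fitted and their weights: with only the 3 arrays of the mutated line 820 genes passed, and with array weights 454. Why was not tested. Without replicate 1 the number was 0.

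Of the heat lists, 3 stood above other genes in 35S:mutHSFB1 roots, and HSP70, HSP90 and HSP100 did not (adjusted p = 0.218). Other heat-induced genes had a median of 0.52 (camera adjusted p = 5.16e-12, and adjusted p = 0.125 with an estimated correlation), and 8 of the 14 passed when adjusted over the list alone. Small HSP genes had a median of 0.25 (adjusted p = 6.90e-05, and adjusted p = 0.456 with an estimated correlation), with 5 of 13 passing when adjusted over the list alone, HSP15.7 highest at 0.59 ± 0.15. The heat shock factor family had a median of 0.036 (adjusted p = 3.92e-06, and adjusted p = 0.292 with an estimated correlation), with 5 higher and 1 lower when adjusted over the list alone. That test includes the overexpressed HSFB1. The other 18 members had a median of 0.030 and a mean of 0.18 (adjusted p = 2.94e-04, and adjusted p = 0.456 with an estimated correlation). Among the other lists that stood higher were phosphate starvation (adjusted p = 5.55e-07, and adjusted p = 0.292 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone. The circadian clock list had adjusted p = 8.79e-06, and adjusted p = 0.292 with an estimated correlation, with PRR7 at 0.66 ± 0.09 and 3 higher adjusted over the list alone. Iron deficiency (adjusted p = 0.00170, and adjusted p = 0.479 with an estimated correlation; 3 higher adjusted over the list alone, BHLH101 highest at 0.80 ± 0.14) and auxin genes (adjusted p = 0.0178, and adjusted p = 0.479 with an estimated correlation) were higher too.

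Other lists stood lower in 35S:mutHSFB1 roots. Root hair (adjusted p = 0.00564, and adjusted p = 0.639 with an estimated correlation) and salicylate defence genes (median -0.13, adjusted p = 0.0133, and adjusted p = 0.639 with an estimated correlation) did. So did nitrate response (adjusted p = 0.0161, and adjusted p = 0.292 with an estimated correlation) and oxidative stress genes (adjusted p = 0.0202, and adjusted p = 0.517 with an estimated correlation). Cell division genes were at adjusted p = 0.0403, and adjusted p = 0.694 with an estimated correlation. Every one of these calls was lost with the estimate. Lists not past camera were HSP70, HSP90 and HSP100 (0.218), endodermis (0.218), abscisic acid (0.0570), folding (0.495), housekeeping (0.491), photosynthesis (0.725) and jasmonate (0.725), of which 3 HSP70, HSP90 and HSP100 genes, 1 folding gene and 1 abscisic acid gene passed adjusted over the list alone. The jasmonate list had a median of -0.019 and a mean of -0.17 but ranked upward, the HSP70, HSP90 and HSP100 and the folding lists had medians below 0 and means above it, and the abscisic acid list had a median of 0.12 and a mean of -0.11.

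The lines were also compared with each other. By the series design the mutation lies in the repression domain of HSFB1. How far it alters the protein was not measured here, and the lines may differ in more than the mutation. CYP71A12 separated them most (6.23 ± 0.35, adjusted p = 6.58e-04), followed by AT5G40590 (5.46 ± 0.31), CYP706A1 (5.24 ± 0.15), PLA2A (5.16 ± 0.36) and CDEF1 (4.99 ± 0.10). At the other end stood MRN1 (-4.22 ± 0.34, adjusted p = 0.00144), TIP2;3 (-3.58 ± 0.47), CYP71B2 (-3.00 ± 0.29) and the anion channel homologue SLAH1 (-2.51 ± 0.14). Heat shock factors HSFA7A (-1.81 ± 0.28), HSFB2A (-1.45 ± 0.22) and HSFA4A (-0.92 ± 0.15) were lower with intact than with mutated HSFB1, and HSFA8 (1.13 ± 0.11) and HSFA6B (1.00 ± 0.14) were higher. HSFA2 did not pass (-0.93 ± 0.30, adjusted p = 0.104).

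Of 19911 genes, 2893 (14.5%) differed between the lines, 1611 higher and 1282 lower in 35S:HSFB1, and 1004 of them at least 2-fold. All of the 2825 that were also called in 35S:HSFB1 had the same sign there, but both comparisons use the same 35S:HSFB1 arrays. The count depended on single arrays: it was 1347 (1010 higher and 337 lower) without replicate 1 of either line and 1346 (1009 and 337) within the shared slide. It was 4877 (2319 higher and 2558 lower) without 35S:HSFB1 replicate 3, and 890 (598 and 292) or 957 (668 and 289) without replicate 2 or 3 of the mutated line. The calls of HSFA7A and HSFB2A were lost without replicate 1 of either line or without mutated replicate 2, that of HSFA4A in these and without mutated replicate 3, and that of HSFA6B without mutated replicate 2, while HSFA8 kept its call in all of them.

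Chaperone genes went both ways in this difference. HSP17.4-CI (2.47 ± 0.25), HSP17.6C-CI (2.36 ± 0.21), HSP15.4-CIV (1.27 ± 0.23) and HSP70-5 (1.73 ± 0.12) were higher with intact HSFB1. ERDJ3A (-1.79 ± 0.21, adjusted p = 0.00474), HSA32 (-1.11 ± 0.22) and HSP101 (-0.93 ± 0.18, adjusted p = 0.0214) were lower. The small HSP list had a median of -0.28 and a mean of 0.31, and camera ranked it downward without a call (adjusted p = 0.929). Salicylate genes again stood out: 9 of 14 were higher (11 adjusted over the list alone), led by PBS3 at 3.55 ± 0.19, WRKY38 at 3.22 ± 0.32 and WRKY54 at 3.00 ± 0.16. Camera gave adjusted p = 2.01e-07, and adjusted p = 0.963 with an estimated correlation. Of 18 endodermis genes 4 were lower, among them CASP5 (-0.93 ± 0.22), ABCG6 (-0.60 ± 0.11) and CASP2 (-0.59 ± 0.14), and 8 lower and 1 higher adjusted over the list alone. Camera gave adjusted p = 6.43e-04, and adjusted p = 0.963 with an estimated correlation. No other list passed (lowest adjusted p = 0.172). NRT2.1 (3.82 ± 0.21), GH3.3 (4.23 ± 0.78), F6H1 (2.80 ± 0.16), CHIB (2.15 ± 0.12) and PLDZ2 (1.92 ± 0.27) were higher with intact HSFB1. NIA1 (-2.02 ± 0.14), COPT2 (-1.84 ± 0.29), MGD2 (-1.40 ± 0.13) and COR47 (-1.06 ± 0.16) were lower. Among all 69 named genes called in the difference, 18 lost their call without replicate 1 of either line, 27 without mutated replicate 2 and 25 without mutated replicate 3. Of those in this paragraph, HSP101, HSA32, CASP5, CASP2 and GH3.3 lost it in each of these, HSP15.4-CIV, ABCG6 and COR47 without mutated replicate 2 or 3, and PLDZ2 without mutated replicate 2.

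**Figure D2:**
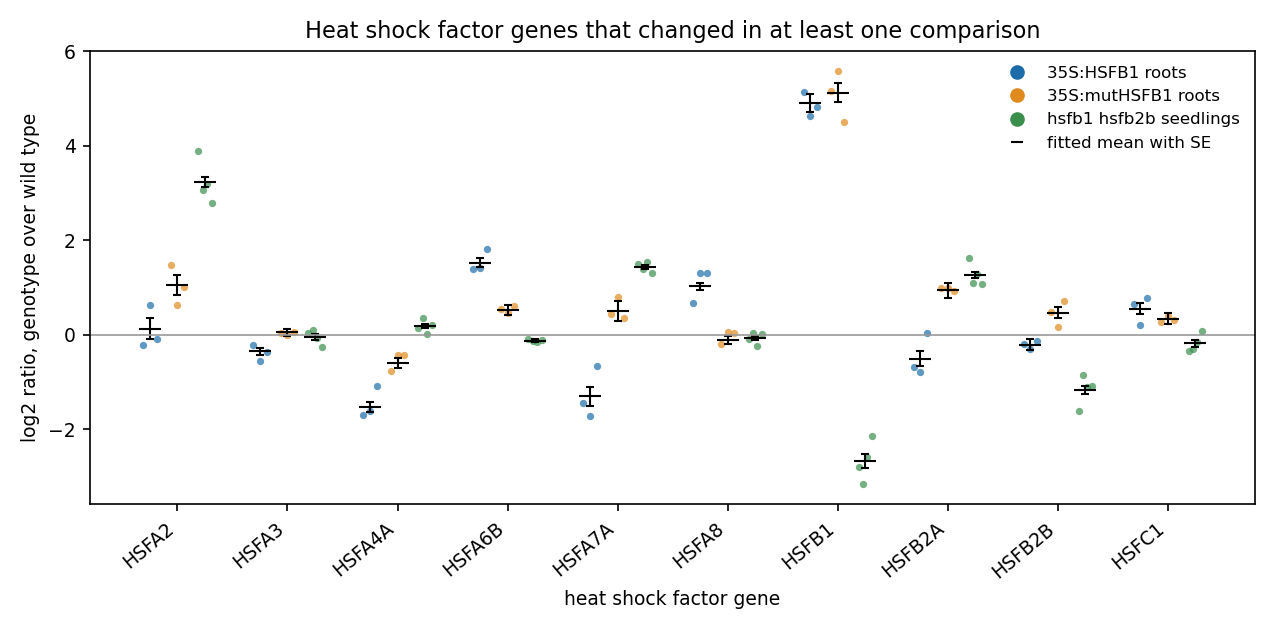
Log2 ratio of genotype over wild type for the heat shock factor genes past the threshold in at least 1 comparison. Coloured points are arrays and black marks the fitted mean with its SE, n = 3 for each root line and n = 4 for seedlings; HSFA2 was at 3.23 and HSFA7A at 1.43 in the knockout.

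Several, but not most, of the tested heat genes were called higher in hsfb1 hsfb2b seedlings that had not been heated. HSFA2 (AT2G26150) rose 9.41-fold (log2 3.23 ± 0.11, n = 4, adjusted p = 1.68e-04), HSFA7A rose by 1.43 ± 0.04 (adjusted p = 9.61e-05) and the class B gene HSFB2A rose by 1.27 ± 0.06 (adjusted p = 4.72e-04). The DnaJ-domain co-chaperone genes AT1G71000 and AT2G20560 rose by 3.74 ± 0.08 (adjusted p = 3.28e-05) and 1.42 ± 0.05. HSP17.8-CI rose by 1.85 ± 0.14, HSP17.6A-CI by 1.41 ± 0.07 and the RING-domain gene AT1G14200 by 1.27 ± 0.06. The lowest gene was MRD1 (AT1G53480), named for lower expression in a methionine-overaccumulating mutant, which fell 32.3-fold (log2 -5.01 ± 0.15, adjusted p = 1.04e-04). AT4G33720, among the highest genes of the overexpressor, fell by 1.43 ± 0.18 here (adjusted p = 0.0244), while AIR1, an auxin-induced gene of root cultures, fell by 0.76 ± 0.11 and the vacuolar calcium exchanger gene CAX1 by 0.70 ± 0.08.

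Among 19401 genes tested 281 (1.45%) passed, 219 higher and 62 lower, and 266 had the same direction on all 4 arrays. By fitted values, which ran low in the simulation, 20 changed at least 2-fold, 16 upward and 4 downward. The count was 55 without replicate 2, 112 without replicate 4, 609 without replicate 1 and 611 without replicate 3, and it was 90 with the scanner software's own log ratio. HSFA2, HSFA7A, HSFB2A, HSFB1, AT1G71000 and MRD1 passed with any array left out. They also passed under every processing alternative in which single genes were followed and they were tested. The calls of HSP17.8-CI, AT4G33720, AIR1 and CAX1 were lost without replicate 2, and those of AIR1 and CAX1 also without replicate 4.

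Small HSP genes were the group that moved most in hsfb1 hsfb2b seedlings. Of 11 tested, 7 rose and none fell (9 adjusted over the list alone), with a median of 0.74, and HSP15.7 rose by 0.93 ± 0.07. Camera gave adjusted p = 3.37e-12, and adjusted p = 0.376 with an estimated correlation. Of 19 HSP70, HSP90 and HSP100 genes 2 rose (CLPB4, 0.81 ± 0.05, and CPHSC70-2, 0.31 ± 0.05) and 1 fell (HSP70-2, -0.49 ± 0.05), or 6 and 1 adjusted over the list alone, at camera adjusted p = 0.00771 and adjusted p = 0.376 with an estimated correlation. Of 13 other heat-induced genes 4 rose, among them BOB1 (0.74 ± 0.04) and DREB2A (0.49 ± 0.08), and HOP3 fell by 0.45 ± 0.05, or 7 and 1 adjusted over the list alone. Camera gave adjusted p = 0.00675, and adjusted p = 0.376 with an estimated correlation. The calls of CPHSC70-2, DREB2A and HOP3 were lost without replicate 2, and those of HSP70-2, CPHSC70-2 and DREB2A without replicate 4. ERDJ3A (0.73 ± 0.04) was the 1 folding gene of 13 that rose (2 adjusted over the list alone; camera adjusted p = 0.00771, and adjusted p = 0.391 with an estimated correlation). With the targeted genes, 3 of 19 heat shock factor genes rose and 2 fell, or 5 and 3 adjusted over the list alone, and the family as a list did not pass camera (adjusted p = 0.422), its median (-0.0065) below 0 and its mean (0.13) above. Without the 2 targeted genes it passed upward (adjusted p = 0.0267, and adjusted p = 0.481 with an estimated correlation), with a median of -0.0032 and a mean of 0.37.

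All genes named in the following lists lost their calls without replicate 2, all but IAA29 and GSTU25 also without replicate 4, and LHCA1 also without replicate 3. Auxin genes rose a little: IAA29 (0.71 ± 0.09), IAA19 (0.40 ± 0.07) and IAA5 (0.31 ± 0.05) were among 4 of 10 that passed (5 adjusted over the list alone), at camera adjusted p = 0.00680 and adjusted p = 0.376 with an estimated correlation. PR4 (0.40 ± 0.06) rose among 18 jasmonate and ethylene genes (3 adjusted over the list alone; camera adjusted p = 0.0226, and adjusted p = 0.376 with an estimated correlation). ZAT12 (0.72 ± 0.09) and APX1 (0.39 ± 0.05) rose and GSTU25 (-0.36 ± 0.06) was 1 of 2 that fell among 14 oxidative stress genes (6 and 4 adjusted over the list alone; camera adjusted p = 0.552). LHCB1.3 rose by 0.32 ± 0.05, and LHCB1.1 (-0.64 ± 0.06) and LHCA1 (-0.25 ± 0.04) fell, in the fit, among 23 photosynthesis genes (1 and 5 adjusted over the list alone), which stood lower as a list (adjusted p = 0.00771, and adjusted p = 0.376 with an estimated correlation). The LHCB1 genes are near-identical copies. The arrays did not share a sign for LHCA1 (0.34 and 0.25 with the knockout in Cy5, -0.82 and -0.76 in Cy3) or LHCB1.3 (-0.0020 and 0.0080, then 0.76 and 0.50). No iron deficiency gene of 18 passed over all genes, but 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.376 with an estimated correlation). Nitrate response genes (0 of 6, or 2 adjusted over the list alone) had adjusted p = 0.0484, and adjusted p = 0.566 with an estimated correlation. The 10 housekeeping genes, none called, also had adjusted p = 0.0484, and adjusted p = 0.376 with an estimated correlation. Cell division genes (0 of 15, or 1 lower adjusted over the list alone) stood lower at adjusted p = 0.0262, and adjusted p = 0.625 with an estimated correlation. The 3 seed storage genes tested (1 lower adjusted over the list alone) stood lower at adjusted p = 0.0153, and adjusted p = 0.477 with an estimated correlation. COR15A (0.33 ± 0.04) was called higher among 17 abscisic acid genes (2 adjusted over the list alone, camera adjusted p = 0.0505), but was at -0.098 and -0.022 on the Cy5 arrays and 0.69 and 0.74 on the others. CDF1 (0.33 ± 0.05) rose among 11 clock genes (3 and 2 adjusted over the list alone, camera adjusted p = 0.597), whose median of -0.040 and mean of 0.027 differed in sign. No member passed among 13 salicylate (adjusted p = 0.255), 14 root hair (0.592), 18 endodermis (0.298) and 15 phosphate starvation genes (0.0527), except 1 phosphate gene adjusted over the list alone.

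Of the 205 genes that the knockout raised and that were also tested in roots, 87 were lower in 35S:HSFB1 roots. HSFA7A (-1.31 against 1.43), HSP17.6A-CI (-0.51 against 1.41), ERDJ3A (-0.78 against 0.73) and AT1G14200 (-1.02 against 1.27) moved in opposite directions in 35S:HSFB1 roots and hsfb1 hsfb2b seedlings. Of the 2626 genes lower in 35S:HSFB1 roots these 87 are a small part, but independent lists would share 28.6 (Fisher's exact test, two-sided, p = 1.38e-23). This test and those below treat genes as independent, which they are not, so their p-values may be too low. The overlap was 28 without 35S:HSFB1 replicate 1 (5.79 expected), and without seedling replicates 1 to 4 it was 150, 17 (6.29 expected), 144 and 29. Within the shared slide it was 59 (Fisher's exact p = 4.58e-17). The reverse, as for AT4G33720, held for 17 genes, of which HSFB1 is 1 by construction of the lines. Without the targeted genes it held for 16 where 6.73 were expected (Fisher's exact p = 6.26e-04), and the 87 remained. Shared directions were at the expected number, 25 higher in both against 26.0 (exact p = 0.916) and 9 lower in both against 7.68 (exact p = 0.561). HSFA2, the factor gene that rose most in the knockout, was not among them. With the difference between the lines in place of 35S:HSFB1, 63 genes were lower and raised by the knockout where 13.4 were expected (exact p = 3.01e-26), on the same 35S:HSFB1 arrays.

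Across the 18795 genes tested in both, the fold changes had a Pearson r of -0.125 and a Spearman rho of -0.12 between 35S:HSFB1 roots and the knockout, and an r of -0.0029 between 35S:mutHSFB1 roots and the knockout. Between the root lines r was 0.140 over 19911 genes, where a simulation without any effect but with the shared dye coefficient gave 0.0504. The covariance was 0.0113, against 0.00037 in the simulation and 9.49e-04 from the shared dye coefficient at the mean residual variance, so that coefficient alone gives less than what was seen. The r varied with single arrays: its values with 1 array left out had a standard deviation above the gap from 0.0504, and single arrays of the 2 lines correlated between -0.0022 and 0.430. Whether wild type RNA was shared is not known. Genes are not independent replicates, so no p-value is attached to these correlations, and tissue and age differ between the roots and the seedlings.

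**Figure D3:**
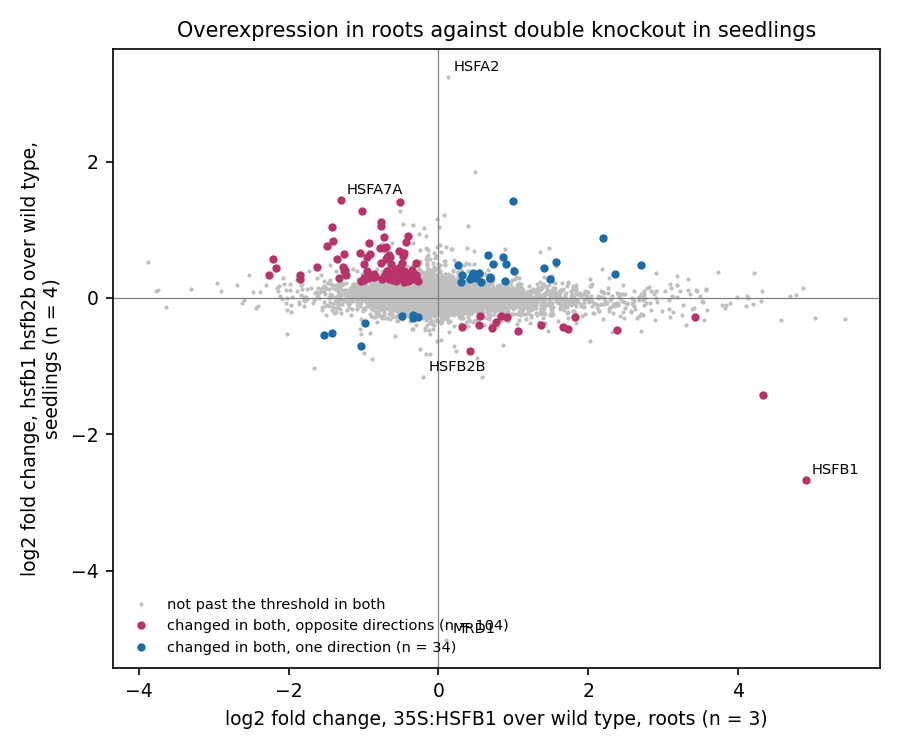
Log2 fold change in hsfb1 hsfb2b seedlings (n = 4 arrays, vertical axis) against 35S:HSFB1 roots (n = 3 arrays, horizontal axis), 1 point per gene over 18795 genes. Genes past the threshold in both are coloured, 87 of them lower in the roots and higher in the seedlings.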

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

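The tests of shoot tissue and of shared wild type RNA were chosen only after the results were seen, while the difference between the root lines, the search for outlying arrays and the split counts were planned.

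Of 19 tested heat shock factor genes 6 differed between intact and mutated HSFB1, and the family as a list did not pass camera. HSFA7A differed by -1.81 and was below 0 with intact HSFB1 and above 0 with the mutated form, HSFB2A differed by -1.45, HSFA4A by -0.92 and HSFB2B by -0.68. HSFA8 and HSFA6B stood higher with intact HSFB1, by 1.13 and 1.00. The calls of HSFA7A, HSFB2A, HSFA4A and HSFB2B were lost without replicate 1 of either line, and that of HSFB2B also without 35S:HSFB1 replicate 2 or mutated replicate 3. Mutated replicate 2 carried the calls of HSFA7A, HSFB2A, HSFA4A and HSFA6B, and mutated replicate 3 also that of HSFA4A. Over all genes 2893 passed the test of the difference. Of the 10 ways to divide the 6 root arrays into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 1, but 10 splits are too few for a share under 0.05.

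Single seedling arrays stood apart for 4 of 62 genes tested, where chance alone marks about 1 in 20. AT5G35940 was at -1.07 on replicate 2 against -0.62 to -0.54 on the others. HOP3, a co-chaperone gene, was at -0.58 on replicate 2 against -0.42 to -0.40, and the glutathione transferase gene GSTU25 was at -0.58 on replicate 2 against -0.31 to -0.27. PR4 was at 0.098 on replicate 1 against 0.47 to 0.52. All 4 values had the sign of the gene's fold change.

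Signal also appeared in probes that carry no gene locus, which no comparison used. In 35S:HSFB1 roots 442 of 3036 such probes passed, 229 higher and 213 lower, and 203 differed between the root lines. In 35S:mutHSFB1 roots 1 passed, the genome-region probe A_84_P733130 (-0.88 ± 0.07, n = 3, adjusted p = 0.00757). In hsfb1 hsfb2b seedlings 5 of 1842 passed: A_84_P735866 (-3.01 ± 0.18, n = 4, adjusted p = 0.00346), A_84_P737484 (1.01 ± 0.05), A_84_P84909 (0.66 ± 0.07), A_84_P213308 (-0.40 ± 0.04) and A_84_P740740 (-0.37 ± 0.04). These 6 probes were named after their values were seen, and what they detect is not known.

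LOX2, RD20 and AT1G23130 were lower than wild type on all 6 root arrays, with LOX2 between -5.22 and -0.87, although none passed in 35S:mutHSFB1 roots, and LOX2 and RD20 are abundant in leaves, so shoot tissue in the wild type root samples was weighed. It stays open in both lines: the photosynthesis list had a median of -0.305 in 35S:HSFB1 roots, with all 22 members below 0 on replicate 2, and of -0.028 in 35S:mutHSFB1 roots, where RBCS1B was at -1.98 ± 0.47. Against it, no member lay below -0.31 on 35S:HSFB1 replicate 3, where LOX2, RD20 and AT1G23130 were at -3.33, -3.59 and -3.15, and the list median was 0.18 on mutated replicate 2 with LOX2 at -3.41, but single arrays do not decide it. Wild type RNA shared between the root arrays may also give both lines the same low values, and this stays open too: the highest correlation of wild type channels between the lines on the shared slide was 0.132, but centring over 4 arrays pulls such correlations down. A response to HSFB1 protein of either form was not tested.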

How the results depend on the processing

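Fits within the shared slide, median signal, the overlaps with arrays left out and without the targeted genes, the heat shock factor list without its targeted genes and the tolerance for correlations were chosen after the data were seen. The cause was not tested for any change below unless it is named.

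Of the named genes past the threshold, 71 of 76 in 35S:HSFB1 roots, the 1 in 35S:mutHSFB1 roots, 64 of 69 in the difference and 18 of 39 in hsfb1 hsfb2b seedlings kept their call under all processing alternatives, replicates left out aside. None turned its sign. Over all named genes and the alternatives so followed, arrays left out included, the direction and side of the threshold were kept in 3579 cases, lost past the threshold in 259, gained in 45 and turned in 50. For lists the numbers were 373, 40, 13 and 20. All 28 list calls made at the preset correlation, that of the housekeeping genes in seedlings included, were lost with an estimated one. Few degrees of freedom in that form, 3 in the roots and 2 in the seedlings, make such a loss likely for any list. In seedlings the HSP70, HSP90 and HSP100 list and other heat-induced genes lost theirs at estimated correlations of -0.034 and -0.065. The losses therefore do not tell whether list members vary together.

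Counts of called genes moved as follows. In 35S:HSFB1 roots 2430 passed with the line's own arrays. With an array left out it was 1731 (without replicate 1, 1172 higher and 559 lower) to 7127 (without replicate 3, 3228 and 3899). The other alternatives gave 3827 (within the shared slide, 2125 higher and 1702 lower) to 6957 (array weights, 3163 and 3794). In 35S:mutHSFB1 roots 25 passed without background subtraction, 23 with the scanner software's log ratio and also 23 with the series matrix, 14 without the dye coefficient, 454 with array weights, 820 with the line's own arrays, 96 with all 10 arrays, 2 with slide as a random block, 0 within the shared slide, and 0 (without replicate 1) to 1 with an array left out. The difference gave 5296 with array weights (2515 higher and 2781 lower) and 1346 within the shared slide (1009 and 337). With an array left out it gave 890 (without mutated replicate 2, 598 and 292) to 4877 (without 35S:HSFB1 replicate 3, 2319 and 2558). Without replicate 1 of either line it gave 1347 (1010 and 337), because the dye coefficient then absorbs the remaining replicate 1. In seedlings 90 passed with the scanner software's log ratio, 88 with the series matrix, 69 without the dye coefficient, 463 with trend and robust, 101 with all 10 arrays, and 55 (without replicate 2) to 611 (without replicate 3). With a replicate block and no dye coefficient the difference gave 2280. Quantile normalisation of average intensity leaves ratios unchanged by construction.

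Salicylate genes held within the shared slide, with a median of 1.21 (camera adjusted p = 5.20e-08) in 35S:HSFB1 roots and 1.32 (2.16e-09) in the difference. Endodermis genes held as well, at -0.24 (0.0345) and -0.33 (2.27e-04). These are values at the preset correlation, and over all arrays both lists lost their calls with an estimated one (adjusted p = 0.814 and 0.963). All arrays on that slide had the genotype in Cy3, so dye bias stays in its comparisons with wild type. In 35S:mutHSFB1 roots the calls of root hair (0.322), salicylate (0.148), nitrate (0.139), oxidative stress (0.104) and auxin genes (0.0722) were lost within the slide, and endodermis (0.00198) and abscisic acid genes (0.0266) gained one. Auxin (0.0459) and cell division genes (0.0265) gained a call in 35S:HSFB1 roots and jasmonate genes (0.0315) in the difference.

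Without its targeted genes the heat shock factor list kept its camera call in 35S:mutHSFB1 roots (adjusted p = 2.94e-04) and gained one in seedlings (0.0267). Neither held with an estimated correlation (0.456 and 0.481). In 35S:HSFB1 roots (0.977) and the difference the list stayed uncalled.

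The 87 genes lower in 35S:HSFB1 roots and higher in the knockout became 28 without 35S:HSFB1 replicate 1, and 150, 17, 144 and 29 without seedling replicates 1, 2, 3 and 4. Within the shared slide they became 59.

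Correlations of fold changes moved to 0.243 between the root lines with the scanner software's log ratio, and with called genes alone to -0.161 between 35S:HSFB1 and the knockout and -0.080 between 35S:mutHSFB1 and the knockout. Without the dye coefficient the last turned to 0.0172.

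The 20 cases in which a list turned direction under an alternative, several of them for the same list, were uncalled before and after. In 35S:HSFB1 roots the HSP70, HSP90 and HSP100 list turned without background subtraction (adjusted p = 0.96), without the dye coefficient (0.968) and within the slide (0.694), and root hair turned without the dye coefficient (0.872) and within the slide (0.272). In 35S:mutHSFB1 roots the scanner software's log ratio turned folding, jasmonate and housekeeping (each 0.972). Leaving out the dye coefficient turned photosynthesis (0.954) and housekeeping (0.976). The shared slide turned HSP70, HSP90 and HSP100 (0.901), folding and jasmonate (both 0.935), photosynthesis (0.332) and housekeeping (0.334). In the difference housekeeping turned with the scanner software's log ratio (0.945), iron without the filter (0.883), small HSPs without the dye coefficient (0.928) and within the slide (0.590), and other heat-induced genes within the slide (0.973).

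Single genes that turned sign were uncalled and most lay close to 0. With the scanner software's log ratio and the series matrix, 35S:mutHSFB1 roots gave HSFA1D at 0.0038 and 0.0038, HSFA5 at 0.041 and 0.041, and HSFA1A at 0.075 and 0.075. The difference gave HSFA1A at -0.046 and -0.046 and HSFA1B at -0.093 and -0.093. The seedlings gave HSFA1E at 0.053 and 0.053, HSFA5 at 0.020 and 0.020, and HSFA1A at -0.021 and -0.021. Without background subtraction HSFA5 was at 0.016 and HSFA1A at 0.016 in 35S:mutHSFB1 roots, HSFA1B at -0.015 in the difference and HSFA1A at -0.019 in seedlings. Without the dye coefficient HSFA1A was at 0.0059 in 35S:mutHSFB1 roots.

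With arrays left out, ranges that crossed 0 in 35S:HSFB1 roots were -0.20 to 0.046 for HSFA1D, -0.17 to 0.00037 for HSFB4, -0.15 to 0.60 for HSFA2, -0.11 to 0.051 for HSFA1E and -0.0037 to 0.11 for HSFA1A. In 35S:mutHSFB1 roots they were -0.085 to 0.020 for HSFA1D, -0.045 to 0.014 for HSFA5, -0.063 to 0.029 for HSFA1A, -0.014 to 0.058 for HSFB4, -0.027 to 0.062 for HSFA1B, -0.12 to 0.074 for HSFA4C and -0.014 to 0.27 for LBD16. In the difference they were -0.49 to 0.12 for HSFB1, -0.19 to 0.091 for HSFA1D, -0.15 to 0.039 for HSFA1E, -0.0048 to 0.11 for HSFA1A and -0.0063 to 0.095 for HSFA1B. In seedlings they were -0.046 to 0.039 for HSFA1D, -0.038 to 0.021 for HSFB3, -0.027 to 0.014 for HSFA1E, -0.044 to 0.027 for HSFA5, -0.016 to 0.027 for HSFA1A, -0.14 to 0.042 for HSFA3, and -0.00063 to 0.073 for HSFA4C.

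Signal over background limits what can be seen: 59.1% to 65.2% of spots per channel were well above background, and genes dim in both channels were not tested.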

Other observations

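The tests of linkage, of dye bias and of a general stress were chosen only after the results were seen, and so was the look at the 87 genes.

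The 87 genes lower in 35S:HSFB1 roots and higher in hsfb1 hsfb2b seedlings included HSFA7A. The AAA ATPase gene AtCDC48B was at -1.43 and 1.04 in the root and seedling comparisons, and ERDJ3A, HSP17.6B-CI, HSP23.5-M, SGT1A, HOP2 and CPHSC70-2 were among them too. The cell wall gene XTH24 (-2.22 in the roots) also belonged. The medians of the 87 were -0.69 in 35S:HSFB1 roots, -0.047 in 35S:mutHSFB1 roots and 0.39 in the knockout. Of them 56 also differed between the root lines. So did 2825 of all 5458 genes called in 35S:HSFB1 roots, and both comparisons use the same 35S:HSFB1 arrays. In 35S:mutHSFB1 roots 38 of the 87 had a ratio above 0, and none of the 87 passed there. These examples were chosen after their values were seen, and no list was tested among the 87.

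Small HSP genes rose in unheated hsfb1 hsfb2b seedlings, by a median of 0.74. Dye bias of the probes as the whole cause is argued against, since over all 11 tested members the median was 0.83 with the knockout in Cy5 and 0.64 with it in Cy3, where such a bias would turn the sign. A general heat or handling stress of the knockout stays open. HSP70, HSP90 and HSP100 genes had a median of 0.090, with HSP101 at 0.090 and HSP90.1 at 0.10, but went both ways (-0.49 to 0.81). At the preset correlation they stood above other genes by camera (adjusted p = 0.00771), as did other heat-induced genes (0.00675). Both calls were lost with an estimated correlation (adjusted p = 0.376 each). Loss of repression of heat genes may explain the pattern too, and these 2 explanations cannot be told apart here. That HSFA2, itself 9.41-fold higher, acted on them was not tested, and related small HSP genes were not examined for probes that read more than 1 of them.

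Genes near the insertions could be lower because of linked sequence of the insertion lines. Within 100 neighbouring genes on either side of HSFB1 and HSFB2B, 2 of the 60 other lower genes were found, AT4G11670 (-0.30) and HOP3 (-0.45), where 0.687 were expected (Fisher's exact p = 0.15). The locus number of AT4G11670 directly follows that of HSFB2B (AT4G11660). The number of such genes is too small to decide whether linkage plays a part.

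Other sign patterns of the arrays were fitted for the comparisons with wild type. In 35S:HSFB1 roots the real pattern gave 5458 genes, 1 of 4 patterns with as many, and the highest other gave 0. In 35S:mutHSFB1 roots the real pattern gave 1 gene, again 1 of 4, and the highest other 0. In the seedlings the real pattern gave 281, 1 of 7 fitted, and the highest other 10. The pattern that follows the dyes could not be fitted with the dye coefficient. These patterns are too few for a share under 0.05.

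PLP3a was the 1 gene of 410 with several probes in the roots whose probes were called in opposite directions in 35S:HSFB1 (-0.25 and 0.21), and none of 366 was in the seedlings.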
